A study of Homo sapiens with 18 samples.

How the data were processed

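RNA of HEK-293 cells, an established line from human embryonic kidney, was measured on 18 Human Genome U133A 2.0 arrays. The 3 lines were labelled WT (wild type), T466 and T469 (both mutant) and were taken untreated or after 6 hours of follicle-stimulating hormone (FSH) at 3 nM. Each of the 6 groups held 3 arrays. WT and T466 shared a harvest label, and T469 carried another, so that line and harvest changed together for T469. The titles of the untreated T466 arrays carry an added suffix that the other untreated groups lack and the labels do not explain. These arrays were taken as untreated from their treatment labels. The labels do not say whether replicates were separate cultures, so that p-values measure only the spread between these samples.

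The deposited values were log2 values that the authors made with GCRMA, which corrects background, normalizes across arrays and summarises probe sets, per the submitters' processing notes, which give no version. Array medians lay between 3.39 and 3.55, and no further scaling was applied. Low values piled up between 2 and 3, the level at which GCRMA leaves probe sets without signal, so that a fold from there depends on that floor. No detection calls were in the table. Only the number of arrays can be given as a limit on precision, since arrays have no counts.

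The table held 22277 probe sets. The 62 control probe sets were used only for RNA quality. Of the rest, 19064 named 1 gene, 1043 named several genes and 2108 were unnamed here, and the last 2 kinds stayed outside the gene tests. Of the probe sets of 1 gene, 19052 were matched to the reference annotation by Entrez ID. For each of the 11963 genes the probe set with the highest mean over all arrays was kept (4310 genes had several). A gene was tested if it reached a log2 value of 4 on 3 arrays, which left 6837 genes and removed 5126.

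Python 3.11.15 with pandas 2.3.3 read the tables, and matplotlib 3.10.9 drew the figures. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 18 arrays, with 12 residual and 3.34 prior degrees of freedom. The 9 contrasts were the FSH effect in each line, the 3 differences of those effects between lines, and the 3 comparisons of untreated lines. Calls had a Benjamini-Hochberg adjusted p under 0.05, and each value after ± is the standard error of the log2 change from limma, unless named as SD, with n = 3 arrays per group. On simulated data of 6837 genes, the test of an FSH effect recovered 65.7% of changes of 0.5 log2, 95.5% of changes of 1 and 98.5% of changes of 2, with 9 false calls among 182. The test of a difference of FSH effects recovered 32.8%, 74.6% and 97.0%, with 6 false calls among 142. The simulated noise was normal, independent between genes and of 1 SD per gene on all arrays. Only 67, 67 and 66 genes were changed by these sizes, in FSH-treated WT arrays. These rates thus leave out correlated genes, arrays of unequal quality and other numbers of changed genes, and may not hold for the real tests.

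The 24 gene lists covered targets of cAMP and CREB, phosphodiesterases, ERK output, SRF and YAP, FSH response genes of granulosa cells, FSH receptor signalling, cholesterol synthesis, the integrated stress and unfolded protein response, hypoxia, heat shock, p53, NF-kB, TGF-beta, WNT, interferon, both cell cycle phases, the clock, ribosomal proteins and oxidative phosphorylation. Markers of neuronal and adrenal lineage, fibroblasts, epithelium and blood completed them. limma's camera tested each list against all other genes with a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and was repeated with an estimated correlation. No blood marker passed the filter, so that 23 lists were tested. Members were counted over all genes tested and adjusted over the list alone.

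Genes named were, for each FSH effect, the 12 largest rises and 8 largest falls among calls whose arrays did not overlap. For each difference of effects they were the 5 largest in each direction, and for each pair of untreated lines the 10 largest. Up to 4 members of each list with the smallest p in WT cells, up to 6 further members that passed in any FSH effect, and a few receptor, kinase and early response genes were added. Groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Genes named outside that rule are marked as chosen after their values were seen.

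Alternatives covered the filter, eBayes with trend and robust, quantile normalization again, centring each array on its median, arrayWeights, a replicate block, the mean of all probe sets of a gene, every probe set on its own, the groups of a comparison alone, and leaving out each array of the compared groups in turn. Values under 4 set to 4, the fit without untreated T469 replicate 1, and the comparison of untreated T469 with untreated T466 were added after seeing the data. RNA quality was compared by an exact permutation test, two-sided, whose smallest p with 3 against 3 arrays was 0.1.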

Results

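The series, by its title, concerns G protein and beta-arrestin signalling of the FSH receptor. FSH is a pituitary glycoprotein hormone whose receptor couples to the G protein that raises cyclic AMP (cAMP). HEK-293 lines labelled WT, T466 and T469 were measured untreated and after 6 hours of 3 nM FSH, with 3 arrays per group and 18 in all. The genotype labels call WT wild type and T466 and T469 mutant, and name no gene. Array medians ranged from 3.39 to 3.55 log2 units.

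The probe set for the receptor gene FSHR read 2.11 ± 0.00 in untreated WT, 2.11 ± 0.01 in untreated T466 and 2.11 ± 0.02 in untreated T469 cells (SD, n = 3). That is the background of the array, so that receptor mRNA was not measurable here. ARRB1, which encodes a beta-arrestin, read 2.64 ± 0.21 (SD, n = 3) in untreated WT cells, and GRK2, a receptor kinase, 2.15 ± 0.01, also near background. GNAS, which encodes the stimulatory G protein subunit, read 13.35 ± 0.06 in untreated WT, 13.62 ± 0.23 in untreated T466 and 13.61 ± 0.09 in untreated T469 cells (SD, n = 3). ARRB2 was unnamed here.

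The FSH effect in WT cells addressed which genes the hormone changed in the line labelled wild type. FSH raised CGA, the common alpha subunit of the glycoprotein hormones and a classical cAMP target, from 4.01 ± 0.52 to 14.33 ± 0.04 log2 units (SD, n = 3), a rise of 10.33 ± 0.26 that corresponds to 1284-fold. NTS (neurotensin) rose by 7.42 ± 0.16, TAC1 (substance P) by 5.61 ± 0.40, CHGB by 5.10 ± 0.24, SCG2 by 4.96 ± 0.09 and CALCB by 3.54 ± 0.26. The nuclear receptors NR4A2 and NR4A3 rose by 4.17 ± 0.11 and 3.89 ± 0.09, and the transcription factors ETV5, MAFF and FOS by 4.44 ± 0.13, 4.36 ± 0.15 and 4.15 ± 0.07. PCK1, a gluconeogenic enzyme, rose by 3.47 ± 0.12. Several of these genes started at background in untreated cells, so that their folds depend on that floor. Standard errors pool the spread of all 6 groups, and arrays at background, which vary little, lower them and the p-values.

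The largest fall in WT cells was that of TXNIP, an inhibitor of thioredoxin, which fell by 3.48 ± 0.10 (limma adjusted p = 2.87e-13). MAP2K6, a kinase upstream of p38, fell by 2.28 ± 0.16, LRRC17 by 2.24 ± 0.30 and the atypical cadherin FAT4 by 1.87 ± 0.22. MPPED2 fell by 1.57 ± 0.15, PHLDA1 by 1.54 ± 0.42, SPAG16 by 1.46 ± 0.21 and CLIC5 by 1.42 ± 0.13. Of 6837 genes tested with limma, 1775 passed, of which 804 rose and 971 fell. At least 2-fold changes were 108 rises and 52 falls. Over all genes tested, the 3 FSH arrays did not overlap the 3 untreated arrays in 45.8%, against a chance share of 10%. Between FSH and untreated WT cells the 3' minus 5' difference of the ACTB control probe sets differed by -0.21 log2 (exact permutation p = 0.3).

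**Figure D1:**
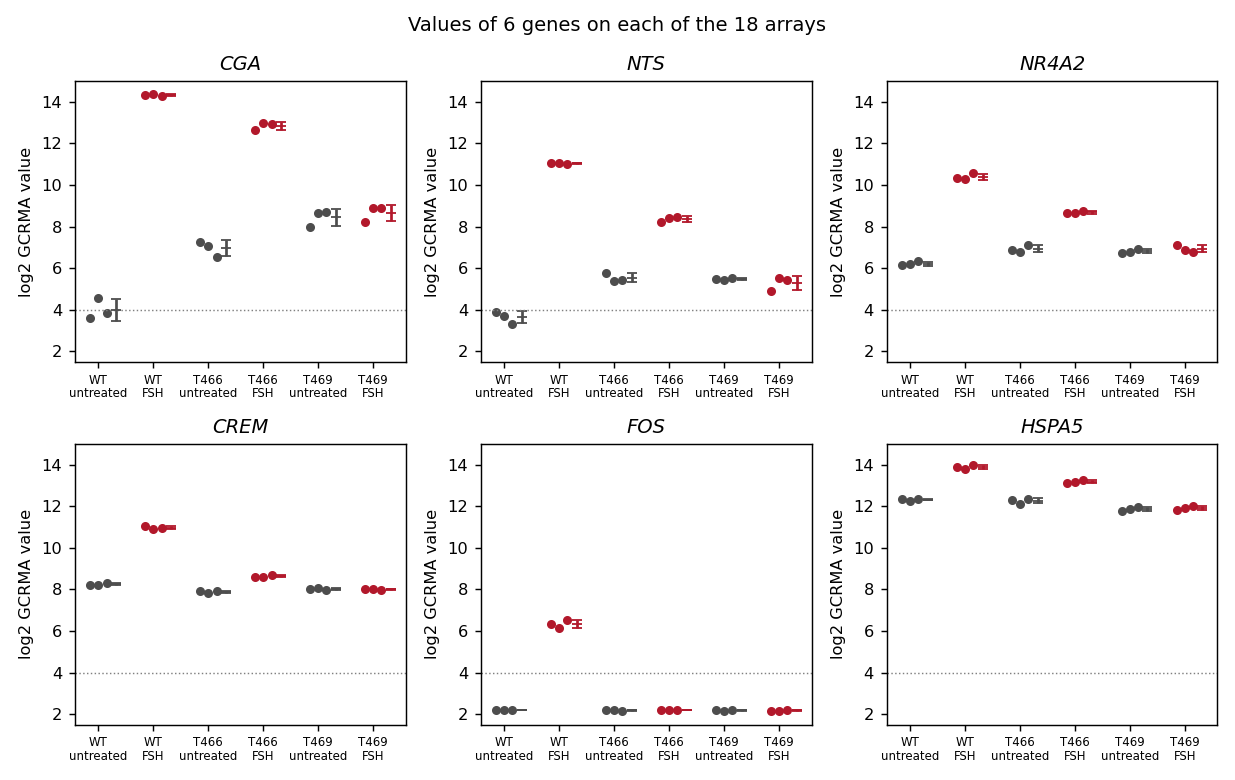
Log2 GCRMA values of 6 genes (vertical axis) in the 6 groups (horizontal axis); each point is an array, bars give mean and SD of 3 arrays, red is FSH, grey is untreated, and the dotted line is the filter value of 4. CGA averaged 14.33 in FSH-treated WT, 12.84 in FSH-treated T466 and 8.68 in FSH-treated T469 cells.

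By gene list, the cAMP and CREB targets shifted most in WT cells. Of 27 tested members 24 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.43e-37; adjusted p = 5.12e-06 with an estimated correlation). Beside CGA and the NR4A genes, RGS2, a regulator of G protein signalling, rose by 2.93 ± 0.08, the kinase SIK1 by 3.46 ± 0.15, NR4A1 by 3.33 ± 0.07 and CREM, which encodes activators and repressors of cAMP response elements, by 2.72 ± 0.06. CITED2 fell by 0.52 ± 0.18 and was chosen after its values were seen. Of 7 tested cAMP phosphodiesterases, the enzymes that degrade cAMP, 6 rose, also 6 adjusted over the list alone, among them PDE4A by 1.88 ± 0.11, PDE8B by 1.39 ± 0.14 and PDE10A by 1.28 ± 0.13 (adjusted p = 3.42e-06; adjusted p = 0.00186 with an estimated correlation). Of 16 ERK output genes 11 rose and 1 fell, or 12 and 2 adjusted over the list alone (adjusted p = 9.9e-07; adjusted p = 0.00567 with an estimated correlation). DUSP6 and DUSP4, phosphatases that act on MAP kinases, rose by 1.59 ± 0.13 and 1.46 ± 0.20, EGR1 rose by 1.46 ± 0.21 and MYC by 0.60 ± 0.15.

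The integrated stress and unfolded protein response list rose in 20 of 22 tested members in WT cells, also 20 adjusted over the list alone (camera adjusted p = 5.43e-23; adjusted p = 0.00135 with an estimated correlation). CHAC1, which degrades glutathione, rose by 3.20 ± 0.09, HERPUD1, a component of endoplasmic reticulum (ER) degradation, by 1.85 ± 0.13, the transcription factors DDIT3 and XBP1 by 1.70 ± 0.10 and 1.63 ± 0.16, and the ER chaperone HSPA5 by 1.57 ± 0.08. Neuronal and adrenal lineage markers rose in 6 of 12 members and 1 fell, or 7 and 1 adjusted over the list alone (adjusted p = 0.00103; adjusted p = 0.0108 with an estimated correlation). SNAP25, a protein of synaptic vesicle fusion, rose by 2.52 ± 0.24. Of 14 p53 targets 7 fell and 0 rose, or 8 and 0 adjusted over the list alone (adjusted p = 0.00103; adjusted p = 0.0146 with an estimated correlation), including DDB2, which fell by 0.87 ± 0.10, and SESN1, which fell by 0.79 ± 0.07.

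Weaker shifts in WT cells lost their call with an estimated correlation. Of 17 cholesterol synthesis genes 7 fell, also 7 adjusted over the list alone, among them LSS, which fell by 0.89 ± 0.13, and DHCR7, which fell by 0.49 ± 0.07 (adjusted p = 0.00441; adjusted p = 0.172 with an estimated correlation). Of 15 hypoxia and glycolysis genes 6 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.00463; adjusted p = 0.138 with an estimated correlation), with hexokinase HK2 up by 1.54 ± 0.11, NDRG1 by 1.27 ± 0.15 and VEGFA by 0.98 ± 0.10. Of 14 heat shock genes 4 rose and 1 fell, or 6 and 1 adjusted over the list alone (adjusted p = 0.0297; adjusted p = 0.244 with an estimated correlation). HSPH1 rose by 0.62 ± 0.11 and HSPB1 fell by 0.39 ± 0.12.

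The other 14 lists did not pass in WT cells, with adjusted p values of 0.0836 for G2/M cell cycle, 0.293 for G1/S cell cycle, 0.293 for SRF and YAP targets, 0.132 for FSH response genes of granulosa cells, 0.132 for NF-kB targets and 0.345 for interferon response. They were 0.883 for FSH receptor signalling, 0.484 for TGF-beta targets, 0.863 for WNT targets, 0.526 for the clock, 0.892 for ribosomal proteins, 0.682 for oxidative phosphorylation, 0.345 for fibroblast and 0.82 for epithelial markers. Single members changed all the same: ISG15, an interferon-induced ubiquitin-like protein, rose by 2.09 ± 0.18 while IFIT1 fell by 1.20 ± 0.21, the YAP targets CCN2 and CCN1 rose by 1.85 ± 0.16 and 1.04 ± 0.12, and the clock genes NR1D2 and DBP fell by 1.40 ± 0.39 and 1.01 ± 0.25. NFIL3, also on the clock list, rose 2.00-fold. Median and mean had different signs in the FSH receptor signalling, TGF-beta, clock and epithelial lists, and the ribosomal protein test pointed up with a median and a mean just under 0.

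The FSH effect in T466 cells addressed which part of the response remained in that line. CGA rose by 5.87 ± 0.26, from 6.97 ± 0.38 to 12.84 ± 0.18 log2 units (SD, n = 3; limma adjusted p = 2.51e-09), NTS by 2.84 ± 0.16 and TAC1 by 2.14 ± 0.40. NR4A2 rose by 1.74 ± 0.11, ETV5 by 1.48 ± 0.13, MAFF by 1.23 ± 0.15, SIK1 by 1.21 ± 0.15 and CREM by 0.77 ± 0.06. ER stress genes rose with them: HERPUD1 by 1.07 ± 0.13, HSPA5 by 0.92 ± 0.08 and the co-chaperone DNAJB9 by 0.69 ± 0.09. PDE10A rose by 0.77 ± 0.13. The falls were those of the splicing factor SRSF5 (fell by 0.65 ± 0.11), MLLT3 (fell by 0.59 ± 0.10), ARHGEF28 (fell by 0.48 ± 0.09), CENPBD2P (fell by 0.44 ± 0.09) and CLEC11A (fell by 0.34 ± 0.06). FOS, SCG2, NR4A1 and RGS2 showed changes of 0.02, -0.00, 0.02 and 0.14, none of which passed. Untreated levels of FOS, SCG2 and NR4A1 were 1.01, 1.00 and 1.01-fold apart between T466 and WT, as for probe sets near background. For these genes a lost rise cannot be told apart from one that stayed below background.

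In T466 cells 26 genes passed with limma, of which 21 rose and 5 fell, and 744 had an unadjusted p under 0.05. The latter number was 441 without untreated T466 replicate 2 and 1176 without untreated T469 replicate 1. Over all genes tested, the arrays of the groups did not overlap in 22.8%, against a chance share of 10%. The untreated T466 arrays, on which this effect rests, carry an added suffix in their titles that the labels do not explain. In WT cells 21 of the 26 passed in the same direction, 2 passed in the opposite one (COBLL1 and CENPBD2P) and 3 did not pass (RSRP1, KLF5 and ARHGEF28); COBLL1, RSRP1 and KLF5 were chosen after their values were seen. The RNA mass of FSH-treated T466 cells differed from that of untreated cells by -13.9 micrograms (exact permutation p = 0.1, the smallest possible). The count was 14 without untreated replicate 2, 15 without FSH replicate 1, 2 or 3, and 79 without untreated T469 replicate 1, an array that enters through the shared spread. It was 95 with arrayWeights and 12 with the T466 arrays alone.

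Among gene lists in T466 cells, the cAMP and CREB targets rose in 7 of 27 members, or 12 adjusted over the list alone (camera adjusted p = 3.16e-21; adjusted p = 0.000105 with an estimated correlation). The integrated stress and unfolded protein response list rose in 5 of 22, or 11 adjusted over the list alone (adjusted p = 7.89e-16; adjusted p = 0.0069 with an estimated correlation). ERK output genes rose in 1 of 16, ETV5, or 2 adjusted over the list alone (adjusted p = 7.82e-05; adjusted p = 0.0165 with an estimated correlation), and phosphodiesterases in 1 of 7, PDE10A, or 2 adjusted over the list alone (adjusted p = 0.00166; adjusted p = 0.0165 with an estimated correlation). The p53 targets shifted down with a median of -0.20 (adjusted p = 7.82e-05; adjusted p = 0.00856 with an estimated correlation), although limma called 0 members over all genes and 5 adjusted over the list alone. Heat shock genes had a median change of 0.11 (adjusted p = 0.00378; adjusted p = 0.182 with an estimated correlation). The TGF-beta targets had a median of 0.15 (adjusted p = 0.0139; adjusted p = 0.266 with an estimated correlation) and the clock genes of 0.11 (adjusted p = 0.0139; adjusted p = 0.193 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.06 (adjusted p = 0.0158; adjusted p = 0.242 with an estimated correlation).

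The FSH effect in T469 cells addressed the same question in the other mutant line. All T469 arrays carried a harvest label that no other line shared, so that a small effect cannot be ascribed to the line alone. CGA read 8.45 ± 0.39 untreated and 8.68 ± 0.39 with FSH (SD, n = 3), a difference of 0.23 ± 0.26 that did not pass (limma adjusted p = 0.786), and NTS, NR4A2 and CREM differed by -0.19 ± 0.16, 0.11 ± 0.11 and -0.00 ± 0.06. The genes that passed all fell: KIF1A, an axonal transport motor, fell by 1.53 ± 0.19, the TGF-beta regulator SKI fell by 1.35 ± 0.21, the Golgi protein GOLIM4 fell by 1.31 ± 0.21, the cadherin CDH8 fell by 0.86 ± 0.13, the lipid droplet protein PLIN2 fell by 0.67 ± 0.11 and the G protein subunit GNG4 fell by 0.54 ± 0.09. GNG4 rose by 0.95 ± 0.09 in WT cells, and the other 5 did not pass there. limma thus called 6 genes, with 0 rises, and 432 had an unadjusted p under 0.05. That number was 222 without untreated replicate 1 and 1091 without untreated replicate 2. Over all genes tested, the arrays did not overlap in 8.66%, below the chance share of 10%.

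No gene list passed in T469 cells, 0 of 23 with limma's camera at either correlation, and 1 list had an unadjusted p under 0.05. That list was the integrated stress and unfolded protein response, with a median change of 0.06 (adjusted p = 0.719), and the cAMP and CREB targets had a median of 0.03 (adjusted p = 0.984). Untreated T469 replicate 1 had 17.4 micrograms of RNA, the lowest of the series, and a residual SD of 0.297 log2, the highest. The ACTB 3' minus 5' difference was higher in FSH-treated than in untreated T469 cells by 0.44 log2 (exact permutation p = 0.1, the smallest possible). Only KIF1A and SKI stayed past without untreated replicate 1, and only GOLIM4 and CDH8 with values under 4 set to 4. The count was 1 without untreated replicate 2 or FSH replicate 3, 2 without FSH replicate 1 or 2, 5 without untreated replicate 1, 0 with a stricter filter (367 at an unadjusted p under 0.05) and 0 with the T469 arrays alone (161 at an unadjusted p under 0.05).

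**Figure D2:**
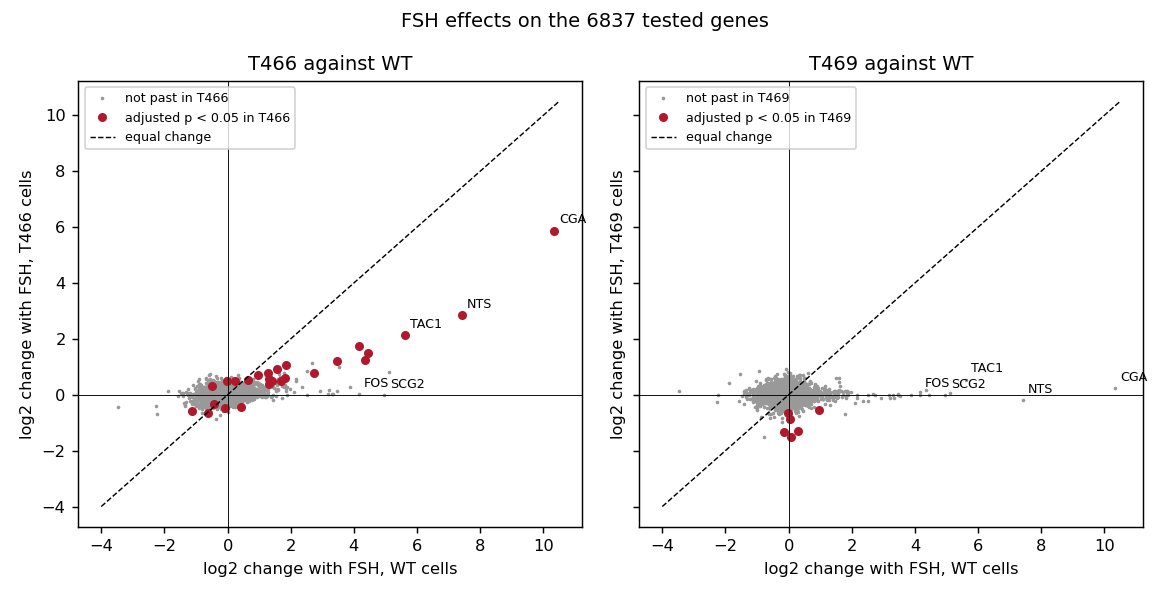
Log2 change with FSH of the 6837 tested genes in WT cells (horizontal axis) against T466 or T469 cells (vertical axis); each point is a gene, red points passed in the line on the vertical axis and the dashed line marks equal change. CGA lies at 10.33 in WT against 5.87 in T466 and 0.23 in T469 cells.

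The differences of FSH effects tested directly whether the lines responded differently. Between T466 and WT cells the effect differed by -4.96 ± 0.13 for SCG2, -4.58 ± 0.22 for NTS, -4.45 ± 0.37 for CGA, -4.30 ± 0.34 for CHGB and -4.13 ± 0.10 for FOS. For CGA, part of this lay in the untreated level, which was 7.79-fold higher in T466 than in WT cells. The untreated WT level of CGA was near the filter value of 4. SCG2 and FOS stayed near background in T466 cells, so that the size of their differences depends on that floor. Genes that fell in WT cells had positive differences, of 3.04 ± 0.14 for TXNIP, 2.01 ± 0.31 for FAT4, 1.87 ± 0.23 for MAP2K6, 1.54 ± 0.42 for LRRC17 and 1.54 ± 0.21 for MPPED2. limma called 800 genes, 393 with a positive and 407 with a negative difference. Of the 26 genes past in T466 cells, 19 also differed from WT by this test, and 7 did not pass it: ARHGEF28 (adjusted p = 0.0535), PDE10A (adjusted p = 0.0811), KLF5 (adjusted p = 0.169), DNAJB9 (adjusted p = 0.216), CLEC11A (adjusted p = 0.643), AHR (adjusted p = 0.684) and SRSF5 (adjusted p = 0.874), with KLF5 and AHR chosen after their values were seen. The count was 485 without untreated T466 replicate 2, 524 without FSH T466 replicate 1, 529 without untreated WT replicate 3 and 1356 without untreated T469 replicate 1, and 1401 with arrayWeights.

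Between T469 and WT cells the effect differed by -10.10 ± 0.37 for CGA, -7.60 ± 0.22 for NTS, -5.07 ± 0.56 for TAC1, -5.03 ± 0.34 for CHGB and -4.96 ± 0.13 for SCG2. For CGA, the untreated level was 21.7-fold higher in T469 than in WT cells, which is part of its difference. SCG2 stayed near background in T469 cells, so that the size of its difference depends on that floor. Positive differences were 3.62 ± 0.14 for TXNIP, 2.29 ± 0.60 for PHLDA1, 2.28 ± 0.31 for FAT4, 2.25 ± 0.42 for LRRC17 and 2.03 ± 0.23 for MAP2K6. limma called 994 genes, 522 positive and 472 negative, and 1616 with arrayWeights. Line and harvest label changed together here, so that a weaker hormone treatment in that harvest cannot be told apart from a line that responds less. Between T469 and T466 cells it called 19 genes, with 18 lower in T469. These included CGA (-5.64 ± 0.37), NTS (-3.03 ± 0.22), SKI (-1.63 ± 0.30), NR4A2 (-1.63 ± 0.15) and KIF1A (-1.59 ± 0.27), while the butyrophilin BTN3A1 was higher (0.95 ± 0.16). That count ranged from 8 to 23 with single arrays of the 2 lines left out, and was 8 with the T466 and T469 arrays alone, 10 with a replicate block, 12 without a filter, with the mean of all probe sets or with values under 4 set to 4, and 29 with arrayWeights.

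The cAMP and CREB targets differed in 20 of 27 members between T466 and WT in either direction, 19 negative and 1 positive, or 22 and 1 adjusted over the list alone (camera adjusted p = 7.85e-33; adjusted p = 1.02e-05 with an estimated correlation). Between T469 and WT 21 were negative, or 22 and 1 positive adjusted over the list alone (adjusted p = 6.75e-39; adjusted p = 3.99e-06 with an estimated correlation). Between T469 and T466 5 were negative, or 9 adjusted over the list alone (adjusted p = 4.48e-16; adjusted p = 0.00043 with an estimated correlation). The stress response list followed, with 15 negative members for T466 against WT, or 16 adjusted over the list alone (adjusted p = 3.19e-15; adjusted p = 0.0081 with an estimated correlation), 16 for T469 against WT, or 19 (adjusted p = 1.81e-20; adjusted p = 0.0021 with an estimated correlation), and 3 for T469 against T466, or 6 and 1 positive (adjusted p = 3.82e-08; adjusted p = 0.0391 with an estimated correlation). Of 23 lists, 6, 9 and 8 passed in the 3 differences, and 5, 6 and 4 with an estimated correlation. The 8 between T469 and T466 became 4 without untreated T466 replicate 1 or untreated T469 replicate 2, 3 without untreated T469 replicate 3 and 5 without FSH T469 replicate 3.

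Across the tested genes, which are not independent replicates, the log2 changes of WT and T466 cells correlated with Pearson's r of 0.39 (jackknife SE 0.124) and Spearman's rho of 0.12. The r was -0.00 (jackknife SE 0.0724) for WT and T469 and 0.15 (jackknife SE 0.160) for T466 and T469, 3 relations in all, and the last was 0.02 without untreated T469 replicate 1. WT and T466 shared 18 rises, against 2.47 by chance, and 3 falls, against 0.710. The 108 genes that rose at least 2-fold in WT cells had a median change of 1.46 there, 0.29 in T466 and 0.01 in T469 cells, with 101 and 105 of them past in the test against WT. The 52 genes that fell as strongly had medians of -1.13, -0.03 and 0.01, with 41 and 45 past. All these sets were chosen on WT values, which inflates the WT medians. It also raises the counts past in the test against WT, which reuses the same WT arrays.

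**Figure D3:**
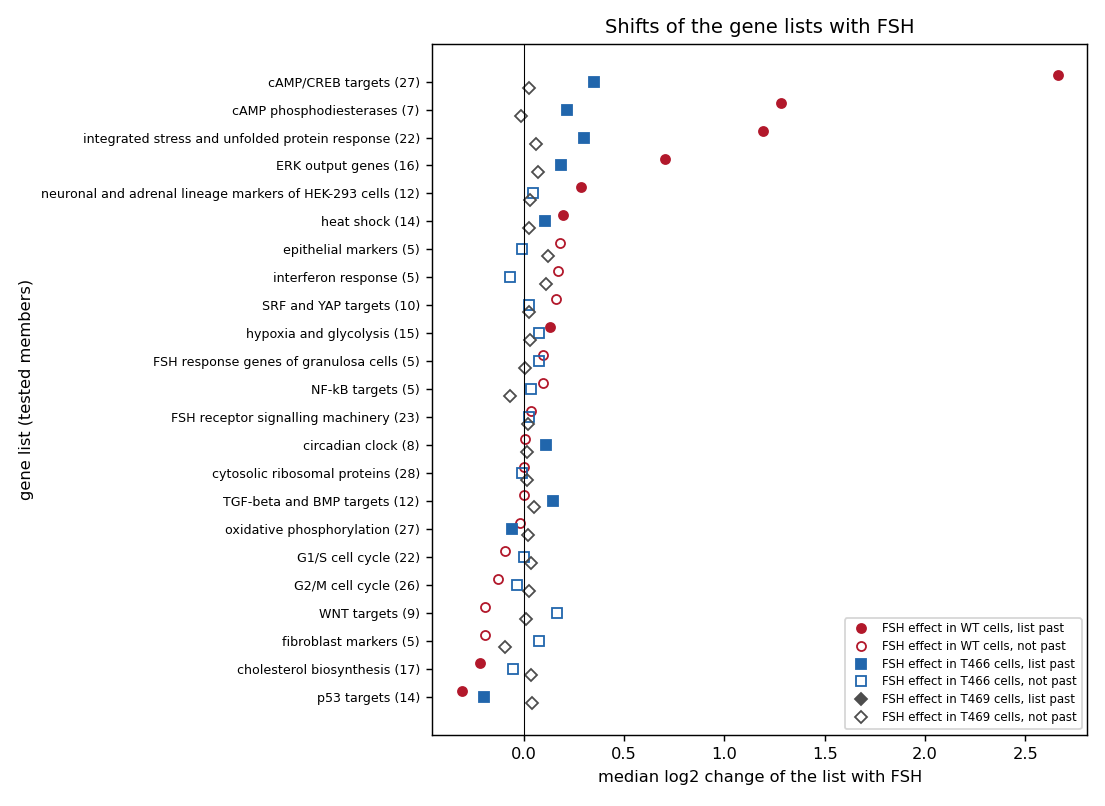
Median log2 change with FSH (horizontal axis) of the 23 tested gene lists (vertical axis, tested members in brackets) in WT (circles), T466 (squares) and T469 cells (diamonds); filled symbols passed camera with the preset correlation. The cAMP and CREB targets had medians of 2.66, 0.35 and 0.03.

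The comparison of untreated lines addressed how the cells differed before the hormone. T466 and T469 cells had much more mRNA of CTSZ, a lysosomal protease, than WT cells (7.62 ± 0.11 and 7.69 ± 0.11 log2), and of the growth factor PTN (5.72 ± 0.12 and 6.73 ± 0.12). ARMCX6 (5.53 ± 0.21 and 5.61 ± 0.21), the microfibril protein MFAP2 (5.17 ± 0.14 and 4.67 ± 0.14), ANXA1 (4.78 ± 0.18 and 4.99 ± 0.18), the neurofilament gene INA (4.73 ± 0.10 and 4.74 ± 0.10), the mismatch repair gene MLH3 (3.95 ± 0.13 and 3.96 ± 0.13) and ARMCX1 (3.92 ± 0.18 and 4.13 ± 0.18) were also higher in both. So were CD44, an adhesion receptor (3.57 ± 0.11 and 3.71 ± 0.11), HOPX (3.46 ± 0.19 and 3.38 ± 0.19), MAPK13 (3.30 ± 0.20 and 3.86 ± 0.20) and CGA (2.96 ± 0.26 and 4.44 ± 0.26). MAOA, which degrades monoamines, was lower (-3.89 ± 0.09 and -3.83 ± 0.09), as were ZNF22 (-2.84 ± 0.27 and -3.11 ± 0.27), CUX2 (-2.38 ± 0.17 and -2.41 ± 0.17), NELL2 (-1.93 ± 0.13 and -2.08 ± 0.13) and RGS7 (-1.92 ± 0.24 and -1.84 ± 0.24).

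The p53 targets were higher in 11 of 14 members in untreated T466, or 12 adjusted over the list alone (camera adjusted p = 1.18e-06; adjusted p = 0.00413 with an estimated correlation), and in 14 of 14 in T469, the same adjusted over the list alone (adjusted p = 7.57e-10; adjusted p = 0.000681 with an estimated correlation). SESN1 was higher by 1.07 ± 0.07 and 0.89 ± 0.07. Chosen after their values were seen, TP53I3 was higher by 2.49 ± 0.13 and 2.87 ± 0.13, and the cell cycle inhibitor CDKN1A by 1.72 ± 0.12 and 1.96 ± 0.12. G2/M genes were lower in 14 of 26 members in T466, also 14 adjusted over the list alone (adjusted p = 0.000125; adjusted p = 0.0122 with an estimated correlation), and lower in 15 and higher in 2 in T469, or 16 and 2 adjusted over the list alone (adjusted p = 0.02; adjusted p = 0.113 with an estimated correlation), with the kinesin KIF11 at -0.82 ± 0.11 and -0.77 ± 0.11. Epithelial markers were higher in 3 of 5 members in T466 (adjusted p = 0.0254; adjusted p = 0.309 with an estimated correlation) and 4 of 5 in T469 (adjusted p = 0.00262; adjusted p = 0.167 with an estimated correlation), including the keratin KRT19 at 1.40 ± 0.13 and 1.54 ± 0.13, both counts being the same adjusted over the list alone.

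Heat shock genes were lower in 7 and higher in 1 of 14 members in untreated T466, the same adjusted over the list alone (camera adjusted p = 0.0254; adjusted p = 0.309 with an estimated correlation), with the co-chaperone STIP1 at -1.81 ± 0.13. In untreated T469 cells, interferon response genes were higher in 4 and lower in 1 of 5 members (adjusted p = 0.0328; adjusted p = 0.167 with an estimated correlation) and neuronal and adrenal markers higher in 6 and lower in 1 of 12 (adjusted p = 0.0114; adjusted p = 0.0667 with an estimated correlation), both the same adjusted over the list alone. INA, NEFM (2.82 ± 0.14) and KIF1A (2.29 ± 0.19) were among the latter. limma called 2906 genes between T466 and WT, 1499 higher and 1407 lower in T466, and 3250 between T469 and WT, 1353 higher and 1897 lower in T469. Over all genes tested, arrays did not overlap in 58.4% and 54.5%, against a chance share of 10%. T469 carried another harvest label than WT, so that line and harvest changed together in the differences that T466 did not share. The 4 lists past in T466 became 2 with the arrays of the comparison alone, and the 5 in T469 became 3 with the mean of all probe sets.

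The comparison of untreated T469 with untreated T466 cells was added after seeing the data and also spans both harvest labels. The ACTB 3' minus 5' difference averaged 1.02 log2 in untreated T469, 1.61 in untreated T466 and 1.48 in untreated WT arrays. The untreated T469 arrays had the highest residual SDs of the series (0.297, 0.176 and 0.164 log2). NFAT5, a transcription factor of the osmotic response, was higher in T469 by 3.73 ± 0.45, the ephrin receptor EPHA4 by 3.28 ± 0.24, DCAF16 by 2.85 ± 0.44, the neural transcription factor POU3F2 by 2.56 ± 0.35 and NAA15 by 2.46 ± 0.40. The imprinted gene MEST was lower (-1.36 ± 0.17), as were DENND1A (-1.31 ± 0.19), PUDP (-1.27 ± 0.26) and GDAP2 (-1.22 ± 0.29). limma called 843 genes, 281 higher and 562 lower in T469, a balance that turned to 73 higher and 20 lower with the arrays of the comparison alone. Over all genes tested, arrays did not overlap in 28.3% (chance share 10%). The p53 targets alone passed among the lists, higher in 4 of 14 members, or 5 and 1 lower adjusted over the list alone (adjusted p = 0.00409; adjusted p = 0.0743 with an estimated correlation). The gene count was 401 without untreated T466 replicate 1, 537 without untreated T466 replicate 3, 93 with the arrays of the comparison alone, 1454 with arrayWeights and 1520 with every probe set on its own. The list count was 2 without untreated T466 replicate 1 or 3, 3 without untreated T466 replicate 2 and 7 without untreated T469 replicate 1.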

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

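The tests of WT RNA in the T466 arrays, of a common proportion, of receptor mRNA, of the T469 array that stood apart, of background for genes with both means over 4, of the harvest label and of another preparation were chosen or changed after the result was seen, and the comparison of untreated T469 with untreated T466 cells was added then.

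The FSH effect differed between lines by limma's test of the difference. Between T466 and WT cells 800 genes and 6 gene lists differed, among them TXNIP (3.04 log2), FAT4 (2.01), MAP2K6 (1.87), LRRC17 (1.54) and MPPED2 (1.54) upward, and SCG2 (-4.96), NTS (-4.58), CGA (-4.45), CHGB (-4.30) and FOS (-4.13) downward. Between T469 and WT cells 994 genes and 9 lists differed, with TXNIP (3.62), PHLDA1 (2.29), FAT4 (2.28), LRRC17 (2.25) and MAP2K6 (2.03) upward, and CGA (-10.10), NTS (-7.60), TAC1 (-5.07), CHGB (-5.03) and SCG2 (-4.96) downward. Between T469 and T466 cells 19 genes and 8 lists differed, with BTN3A1 (0.95) upward and CGA (-5.64), NTS (-3.03), SKI (-1.63), NR4A2 (-1.63) and KIF1A (-1.59) downward. In both comparisons with T469 a weaker hormone treatment in its harvest cannot be told apart from a line that responds less. The higher untreated level of CGA in both mutant lines is part of its differences from WT. Sizes for SCG2 and FOS depend on the background of the arrays. Outside the gene tests, 180 of 1174 tested probe sets that name several genes or none also changed with FSH in WT cells, 72 up and 108 down.

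The smaller response of T466 cells was set against RNA of FSH-treated WT cells in the T466 arrays. The 18 genes that rose past the threshold in both lines would need a median share of 24.7%. Over 14 genes lower in untreated T466 than in untreated WT cells by at least 1.5 log2, that share calls for a median change of 0.90 log2. The observed median was 0.16 with an upper quartile of 0.27, which argues against a mixture of that size as the whole cause. Choosing called rises inflates the share and the calculated change, and smaller shares were not tested. Another preparation of the untreated T466 arrays as the whole cause is argued against by the FSH-treated arrays, where over the 160 genes with a 2-fold effect in WT cells T466 fell short of WT by a median of 89.2% of that effect (lower quartile 52.3%). The genes were chosen on that effect, and the FSH-treated WT arrays enter both sides of the percentage, which can raise it. One common proportion of the WT log2 change, 21.1%, is argued against by the scatter over 63 genes, with proportions from -7.67% to 60.3%. Q over its degrees of freedom was 6.57, where the 1% point of chi-square is 1.46, and took the genes as independent. A uniform weakening of the receptor signal need not give equal proportions in log2 and was not tested. The FSHR probe set differed by -0.0032 log2 between untreated T466 and WT cells but lay at background in both, so that a lower receptor level cannot be told apart from weaker coupling of the receptor. A mutation that changes receptor signalling may account for the smaller response, as a hypothesis, since the genotype labels name no gene and these arrays do not test it, and differences of the lines before treatment stay open as well.

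The falls in FSH-treated T469 cells were set against untreated replicate 1, which stood apart from its group, and against values near background. Without that array only KIF1A and SKI stayed past the threshold, but the 6 genes kept a median of 92.0% of their fall, which argues against the array as the whole cause. The calls lost were those of GOLIM4 (-1.31 ± 0.21 before, -1.17 ± 0.23 without it), CDH8 (-0.86 ± 0.13 and -0.77 ± 0.14), PLIN2 (-0.67 ± 0.11 and -0.63 ± 0.12) and GNG4 (-0.54 ± 0.09 and -0.56 ± 0.10). Why these calls were lost was not tested. With values under 4 set to 4, 2 of the 6 stayed past (GOLIM4 and CDH8), and the fall shrank to -0.64 ± 0.18 for KIF1A, -0.74 ± 0.13 for SKI and -0.39 ± 0.07 for PLIN2, so that these 3 calls may rest on values near background. The fall of CDH8 shrank too, to -0.63 ± 0.07, and its mean with FSH, 3.77, was also under 4. For GOLIM4 and GNG4, whose means were at least 5.29, values near background are argued against, and the call of GNG4 ended with its fold unchanged. A response of T469 cells to FSH stays open as a biological explanation.

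The differences of untreated mutant lines from WT were set against harvest, preparation and signalling without added hormone. A harvest effect as the whole cause for T466 is argued against by the design, since the 2906 genes differed between lines of 1 harvest label. Fewer genes, 843, differed between T469 and T466, whose labels differ. That number does not measure harvest, since the line changed too, and it ranged from 93 to 1520 over the alternatives without an array left out. Another preparation of the untreated T466 arrays as the whole cause is argued against by the FSH-treated arrays. Over 1992 genes without a called FSH effect in WT cells, these showed a median of 92.7% of the difference (lower quartile 60.2%). For T469 against WT, harvest as the whole cause is argued against by FSH-treated T466 and WT arrays, of 1 harvest label, which over 2317 genes without a called FSH effect in WT cells showed a median of 69.4% of the difference (lower quartile 31.3%), while for the part that T466 did not share line and harvest changed together and cannot be told apart by those 843 genes. Receptor signalling without added FSH in T466 cells as the whole cause is argued against by direction. Of 914 genes past both in untreated T466 against WT and in the FSH effect in WT cells, 40.5% went the way of the FSH response (51.2% of the 86 with a 2-fold effect). The shared arrays alone give 66.7% in simulations without effects, over all genes and not over called ones. The share was 40.4% to 40.5% with the untreated WT arrays split between the comparisons. That is no separate check, since the genes had been called with all those arrays. Means of untreated T466 and T469 cells differed over 2-fold in 77 genes, against 321 for T466 and 471 for T469 from WT. That argues against divergence of each mutant line on its own as the whole cause. Differences from WT that both mutant lines share may bear on their FSH comparisons with WT, and the labels do not explain them. Divergence of the mutant lines from WT in common was not tested, and for single genes such as CGA signalling without added FSH stays open.

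Other splits of the same arrays into groups of the same sizes were fitted in the same way. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05, so that only real values and the highest of the other splits are given. In genes these were 1775 and 1 for FSH in WT (1 split as large), 26 and 1 in T466 (1), 6 and 2 in T469 (1), 2906 and 0 for untreated T466 against WT (1), 3250 and 1 for T469 against WT (1) and 843 and 6 for T469 against T466 (1). In lists they were 9 and 9 for FSH in WT (4 splits as large), 9 and 8 in T466 (1), 0 and 1 in T469 (10), where limma's camera gave 1 list at an unadjusted p under 0.05, 4 and 5 for untreated T466 against WT (2), 5 and 1 for T469 against WT (1) and 1 and 0 for T469 against T466 (1). For the differences of FSH effects 100 splits were drawn. In genes, 2 of 100 were as large for T466 minus WT (800, highest other 883). The number was 1 for T469 minus WT (994 and 988) and 1 for T469 minus T466 (19 and 16). In lists, 32 were as large for T466 minus WT (6, highest other 12). They were 4 for T469 minus WT (9 and 9) and 2 for T469 minus T466 (8 and 8). These shares cannot decide about chance, since the splits do not stand for lines with equal FSH effects. Splits that mixed the arrays of both lines moved FSH effects into the spread within groups, and called at most 2, 1 and 3 genes. Their groups still held unequal numbers of FSH arrays, so that lists could shift, up to 12, 8 and 3. The high other gene counts came from splits that left the arrays of 1 line unmixed, and so kept the FSH effect of that line in them.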

How the results depend on the processing

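The fit with values under 4 set to 4, the genes kept without untreated T469 replicate 1 and the comparison of untreated T469 with untreated T466 were chosen after seeing the data; no named call changed sign under the alternatives run. With every probe set on its own, 537 of the genes called for FSH in WT had several tested probe sets. Of these, 4 (BTG3, FKBP1A, SKP2 and SRSF11, chosen after their values were seen) had another probe set called the opposite way. Values that moved by more than 1.5 times were as follows. With arrayWeights, genes were 95 for FSH in T466, 11 in T469, 1401 for T466 minus WT, 1616 for T469 minus WT, 29 for T469 minus T466 and 1454 for untreated T469 against T466. With only the groups of the comparison they were 12 in T466, 0 in T469 (limma, 161 at an unadjusted p under 0.05), 8 for T469 minus T466 and 93 for untreated T469 against T466. FSH in T469 gave 1 gene without a filter, 0 with a stricter one (limma, 367 at an unadjusted p under 0.05), 2 with a replicate block and 2 with values under 4 set to 4. T469 minus T466 gave 12 without a filter, 10 with a replicate block, 12 with the mean of all probe sets and 12 with values under 4 set to 4, and untreated T469 against T466 gave 1520 with every probe set on its own.

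With an estimated correlation, lists fell to 5 for FSH in T466, 4 for T469 minus T466, 2 for untreated T466 against WT, 1 for T469 against WT and 0 for T469 against T466 (limma's camera, 8 at an unadjusted p under 0.05 with the preset correlation). Untreated T466 against WT gave 2 lists with its groups alone, T469 against WT 3 with the mean of all probe sets, and T469 against T466 gave 5 without a filter, 3 with a stricter one, 3 after quantile normalization, 2 after centring, 6 with arrayWeights and 3 with the mean of all probe sets.

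Leaving out each array of the compared groups in turn, and untreated T469 replicate 1 from every comparison, gave 14 to 79 genes for FSH in T466, 1 to 5 in T469, 485 to 1356 for T466 minus WT, 8 to 23 for T469 minus T466 and 401 to 953 for untreated T469 against T466. For FSH in WT it gave 1286 to 2397, for T469 minus WT 684 to 1164, and for untreated T466 and T469 against WT 2436 to 3502 and 2713 to 3251. Lists ranged from 3 to 9 for T469 minus T466 and 1 to 7 for untreated T469 against T466. Without untreated T469 replicate 1 all 1775, 26 and 800 genes called for FSH in WT, in T466 and for T466 minus WT were kept, as were 875 of 994 for T469 minus WT, 2725 of 3250 for untreated T469 against WT and 573 of 843 against T466. Why a count moved was not tested, apart from the fewer arrays or genes in some fits. The share of genes higher in untreated T469 than T466 moved from 33.3% to 47.4% with centring and to 78.5% with the groups of the comparison alone, where the balance turned over. The share of positive differences of T466 minus WT moved from 49.1% to 57.1% with centring. Replicate numbers did not pair the arrays: 6 of 18 matched best an array of their own number. Of the named calls, 100 of 140 for FSH in WT, 6 of 19 in T466 and 0 of 6 in T469 stayed past in every alternative. Genes near a value of 4, such as KIF1A and FOS, are limited by the background of the arrays.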

Other observations

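The gene families, and the test of ER genes against amino acid genes, were chosen after the result was seen. Both were picked from the same changes, so that the counts by limma below test no grouping. Amino acid supply genes may have risen as a group with FSH in WT cells, as a hypothesis: of 14 tested amino acid transporters 8 rose and 3 fell (SLC7A5, an importer of large neutral amino acids, rose by 1.97 log2), and of 16 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 10 rose, with GARS1 at 0.82 and YARS1 at 0.70. Of 11 precursors of secreted peptides and granins 8 rose, NPY and GAL among them by 0.46 and 0.49. Of 11 dual-specificity phosphatases 6 rose and 1 fell. All 3 tested protocadherins fell: PCDH9 fell by 1.40, PCDH7 fell by 1.03 and PCDH17 fell by 0.84. Zinc finger genes with ZNF symbols showed 13 rises and 24 falls among 149, near the 17.5 and 21.2 that the share over all genes gives.

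In T466 cells 3 of the peptide genes rose, and limma called 0 rises in the other 5 families, where 744 of all genes tested had an unadjusted p under 0.05. ER folding and degradation genes kept a larger proportion of their WT rise in T466 cells, with a median of 32.9% over 14 genes against 13.5% over 19 amino acid stress genes. The difference of 19.4 percentage points is no evidence, since both lists were written after these genes' changes had been seen, and it may serve only as a hypothesis that T466 cells keep the ER branch of the stress response better.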
